A study of Mus musculus with 6 samples.

How the data were processed

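RNA was sequenced from 6 mouse grafts of PTEN-CaP2 prostate cells, 3 from vehicle-treated and 3 from pegvisomant-treated hosts. Per the labels' protocols, libraries were made from total RNA with a stranded kit. The labels name the vehicle as phosphate buffered saline in one field and sterile saline in another. The series design calls the samples biological replicates. The submitters' processing notes name bcl2fastq 2.20.422, STAR 2.5.3a, RSEM 1.3.0 and the GRCm38 build, and the annotation release and strand setting are not given in the sources used here. Per the file headers, the deposited values are RSEM expected counts per Ensembl gene, 1 file per library, with an effective length in bases per gene and library that the authors' files also give. Reads shared between near-identical genes are split by estimation in expected counts, which bears most on ribosomal protein, histone, Mup and major histocompatibility genes and their pseudogenes.

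Expected counts were rounded to whole numbers. In each library between 4182 and 5736 genes had a fractional value. Of 51912 gene IDs, 51633 had a symbol in the gene name table, and coordinates were taken from GENCODE M21 on GRCm38. Total counts were between 13516141 and 46671009 per library. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom between 60.6 and 659, so that no library appeared to be deposited more than once within a group. Pairs across the groups were not checked in this way.

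Genes were filtered with filterByExpr (minimum count 10, minimum total count 15), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, two-sided, with all 6 libraries, no covariate and Benjamini-Hochberg adjusted p under 0.05. Fold changes are pegvisomant against vehicle on the log2 scale with a prior count of 0.125, and their standard errors were taken as the fold change over the square root of the F statistic. Values per library are TMM-scaled CPM for genes tested, and CPM of the library total for marker genes of other tissues and for lists summed as a percent. The 34 gene lists were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM, adjusted over the 34 lists, and again with an estimated correlation and with fry, which asks whether the members of a list move on balance one way and makes no comparison with other genes. With 3 libraries against 3 an exact permutation test has 10 splits and cannot give a p under 0.1.

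The comparison, the test, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule named 11 genes of the growth hormone pathway and related markers whatever their test, then up to 12 genes per direction that passed, did not overlap between groups and had a mean of at least 2 CPM, leaving out symbols of predicted genes, clones and pseudogenes (Gm or LOC with a number, Rik, clone names and -ps). Where fewer than 5 qualified in a direction, it took those with the smallest unadjusted p under the same CPM and symbol rule to make 5, and up to 4 members with the smallest p from each list described. Lists of hepatocyte, adrenal cortex, bone and class II histocompatibility genes were chosen after the data were seen. They were not tested as lists, and serve to give levels per library, to count their members among calls and, for the class II gene H2-Eb1, as a denominator. In the bone list of 17 genes Spp1 was at 3720, 9640 and 11800 CPM in vehicle replicates 1, 2 and 3 and 4960, 2480 and 2130 CPM in the pegvisomant libraries, while the other 16 genes were all highest in pegvisomant replicate 1. The class II list of 7 genes took between 0.0178 and 0.0645% of a library.

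Alternatives were DESeq2 1.42.0, limma-voom with and without quality weights, other scalings (the size factors of DESeq2, upper quartile, library totals alone), no filter on low counts and a stricter one (1 CPM in 3 libraries), effective length offsets, mitochondrial genes left out, the kidney tubule signal as a covariate (the mean of both tubule lists, so that this fit is no test of those lists), a replicate block, a test against 1.5-fold and leaving out each library. A robust prior, removal of a trend on gene length, the use of vehicle replicate 2 alone, in which that library is assumed to vary like the others, and an estimated correlation without vehicle replicate 1 were added after the data were seen. The steps were tested on simulated data with 200 changed genes among 18348 in 3 simulations. edgeR recovered 0% of genes changed 2-fold, 7.46% at 4-fold and 51.5% at 8-fold, with 8 of 54444 unchanged genes called, and DESeq2 recovered 7.46, 60.2 and 90.4%, with 224 unchanged genes called. In separate simulations with genes drawn independently, only the cholesterol synthesis list was shifted, by 1 log2 unit. There camera called that list in 3 of 3 runs, and 1 of 99 other lists. These runs cannot show how camera behaves on correlated lists, and the estimated correlation in the data was 0.94 for ribosomal proteins.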

Results

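Gene expression was measured by RNA sequencing in grafts of PTEN-CaP2 cells, a mouse prostate cancer line derived from a tumour with deleted Pten, grown under the kidney capsule of male nude mice. Each graft started from 350000 cells in a 25 µL collagen pellet, placed when the host was 10 weeks old. After 3 weeks of growth the hosts received 100 mg/kg pegvisomant, a growth hormone analogue that blocks the growth hormone receptor, or vehicle, with 3 injections per week for 3 weeks, and grafts were collected 3 days after the last injection. There were 3 biological replicates per group. The libraries held 23947517, 35166331 and 45692656 counts in vehicle replicates 1, 2 and 3, and 38241188, 13516141 and 46671009 in pegvisomant replicates 1, 2 and 3. A floor of 3 counts corresponded to between 0.0643 and 0.222 CPM (counts scaled to the library total), for counting error only. The comparison asked which transcripts of the graft differed after growth hormone receptor blockade.

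Grafts from pegvisomant-treated hosts had lower levels of gene groups for glycolysis, cholesterol synthesis, ribosomal proteins and cell division, and higher levels of kidney tubule genes, by camera with a preset correlation. That test called 13 lists, and other splits of the 6 libraries gave between 9 and 16. With an estimated correlation 0 lists passed (smallest adjusted p = 0.79) and by fry 0 (smallest adjusted p = 0.338). With the kidney signal as a covariate the median was 0.17 for ribosomal proteins and -0.14 for proliferation. That fit rests largely on vehicle replicate 1, the vehicle library with the most kidney tubule counts. Among single genes, Igfbp3, which encodes a carrier of insulin-like growth factors, was at 578 ± 145 CPM (SD, n = 3) with vehicle and 191 ± 11.6 CPM with pegvisomant, and the pegvisomant libraries all lay below the vehicle libraries. Scd1, a desaturase that makes monounsaturated fatty acids, was at 594 ± 211 CPM with vehicle and 169 ± 44.5 CPM with pegvisomant. Over all 6 libraries edgeR called 0 genes and DESeq2 called 290, Igfbp3 and Scd1 among them. Over 3 simulations of this design together DESeq2 called 224 of 54444 unchanged genes and edgeR 8, so a DESeq2 call alone is weak evidence. Limma-voom with quality weights, which gave vehicle replicates 1, 2 and 3 weights of 0.29, 3.33 and 0.555, called 3018 genes. Without vehicle replicate 1, which also held liver transcripts, edgeR called 1956 genes, 1103 higher and 853 lower. The class II histocompatibility gene H2-Ea had at most 8 counts in a vehicle library and at least 463 in a pegvisomant library. A difference in genotype between the groups therefore stays open.

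The edgeR quasi-likelihood test over 18348 genes called 0 genes at an adjusted p of 0.05, with a smallest adjusted p = 0.302. At an unadjusted threshold of 0.05 there were 3010 genes, 1507 higher and 1503 lower, where chance gives 917 on average. That average is no baseline for a single split, since other splits of the 6 libraries gave between 160 and 3410 genes. DESeq2 called 290 genes, 177 higher and 113 lower, limma-voom called 0, and limma-voom with quality weights called 3018. The groups did not overlap for 4478 genes, or 24.4% of those tested, where chance gives 10% on average. The biological coefficient of variation was 53.2%. Upper-quartile scaling and library totals alone moved the median of all genes by 0.16 and 0.17 on the log2 scale, and turned the split of genes at the unadjusted threshold to 2120 higher and 670 lower, and to 2207 higher and 563 lower. In simulated data of this design edgeR recovered 0% of genes changed 2-fold, 7.46% of those changed 4-fold and 51.5% of those changed 8-fold. DESeq2 recovered 7.46, 60.2 and 90.4%. Over 3 simulations with 200 changed genes each, DESeq2 also called 224 of 54444 unchanged genes, against 8 by edgeR. The share of unchanged genes among the DESeq2 calls was thus well above 0.05.

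Transcripts of other tissues differed between libraries. The 64 genes of both kidney tubule lists took 0.654, 0.0917 and 0.0634% of counts in vehicle replicates 1, 2 and 3, and 0.846, 0.745 and 1.43% in pegvisomant replicates 1, 2 and 3. A hepatocyte list of 25 genes, chosen after the data were seen, took 4.48% of vehicle replicate 1 and at most 0.0496% of any other library, with Alb, the gene for serum albumin, at 18700 CPM. An adrenal cortex list of 14 genes, chosen likewise, took 0.566% of vehicle replicate 3 and at most 0.0201% elsewhere, with the steroidogenic genes Star at 1130 CPM and Cyp11b1 at 828 CPM. Pegvisomant replicate 1 held the bone matrix gene Ibsp at 2840 CPM and Col1a1 at 33300 CPM, against at most 118 and 4180 CPM in any other library. The basal keratin Krt5 had at most 1 count in any library. The luminal keratin Krt8 ranged from 6.15 CPM in vehicle replicate 3 to 152 CPM in vehicle replicate 1, the library with the liver transcripts.

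**Figure D1:**
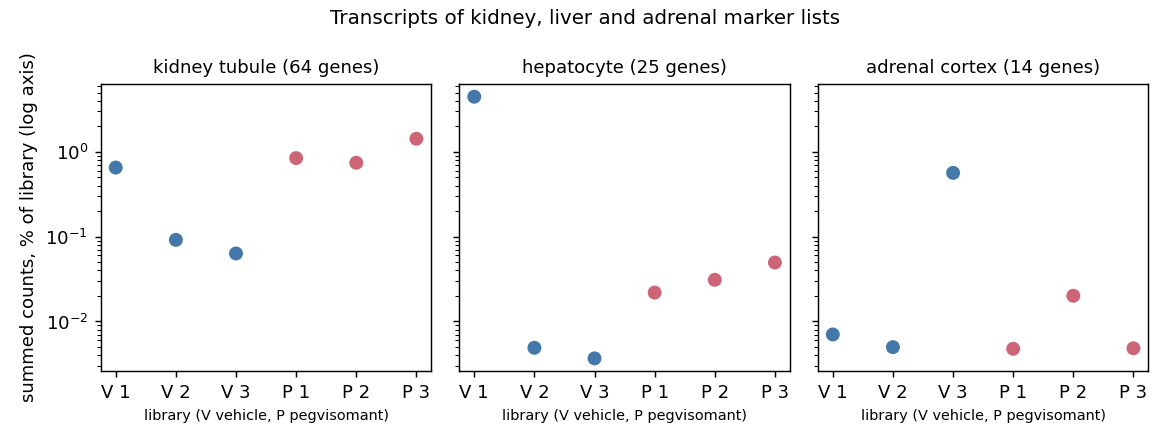
Summed counts of the kidney tubule, hepatocyte and adrenal cortex lists as a percent of each library, on a log axis, with 1 point per library (V, vehicle; P, pegvisomant). The hepatocyte list reached 4.48% in vehicle replicate 1, the adrenal list 0.566% in vehicle replicate 3, and the kidney list lay between 0.745 and 1.43% in the pegvisomant libraries.

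Of 34 gene lists fixed before the data were examined, 13 shifted against the other genes by camera with a preset correlation of 0.01, 9 lower and 4 higher. Other splits of the 6 libraries gave between 9 and 16 lists by the same test, so that count did not set the real split apart. Counts of members that passed are those of edgeR unless DESeq2 is named.

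The hypoxia and glycolysis list fell, with a median log2 fold change of -1.10 (adjusted p = 2.6e-09; adjusted p = 0.79 with an estimated correlation). Over all genes tested edgeR called 0 members and DESeq2 called 3, all lower (Slc16a3, Car9 and Slc2a1), while 22 of 33 passed when adjusted over the list alone, all 22 lower, and 24 had an unadjusted p under 0.05. Pdk1, a kinase that inhibits pyruvate dehydrogenase, was at 130 ± 55.8 CPM with vehicle and 40.2 ± 20.1 CPM with pegvisomant, a log2 fold change of -1.69 ± 0.45 (SE). The lactate exporter Slc16a3 had a log2 fold change of -2.21 ± 0.60, the pyruvate kinase gene Pkm -1.57 ± 0.43 and the phosphofructokinase gene Pfkp -0.87 ± 0.20. With the kidney signal, which was higher in the pegvisomant libraries, as a covariate the median was -0.57 (adjusted p = 0.00514).

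The cholesterol synthesis list fell, with a median of -1.17 (adjusted p = 2.6e-08; adjusted p = 0.79 with an estimated correlation). All 25 members had negative fold changes, 16 with an unadjusted p under 0.05, and 0 passed when adjusted over the list alone, while DESeq2 called Msmo1. The median was -0.72 without vehicle replicate 3, -0.77 with the kidney covariate, -0.68 with quality weights and -0.50 against vehicle replicate 2 alone, past the threshold in each. Msmo1 and Fdft1, enzymes of the sterol pathway, had log2 fold changes of -1.72 ± 0.43 and -1.49 ± 0.39. The fatty acid synthesis list also fell (median -0.62, adjusted p = 0.0089; adjusted p = 0.79 with an estimated correlation; 2 of 22 members lower when adjusted over the list alone). Without vehicle replicate 1 this list no longer passed (median -0.76, adjusted p = 0.0665). Its leading members were Scd1, at -1.82 ± 0.33, and the acyltransferase gene Agpat2, at -1.16 ± 0.25. Over all genes DESeq2 called 3 members of this list, Scd1, Agpat2 and Thrsp, all lower.

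The cytosolic ribosomal protein list fell, with a median of -0.88 (adjusted p = 6.5e-11; adjusted p = 0.79 with an estimated correlation) and all 44 members negative, 21 of them at an unadjusted p under 0.05. Rps24 went from 706 ± 104 to 403 ± 38.6 CPM and Rpl23 from 915 ± 197 to 497 ± 47.3 CPM. The proliferation list had a median of -0.58 (adjusted p = 1.2e-08; adjusted p = 0.79 with an estimated correlation), all 45 members were negative, and its leading members were Pcna, the replication clamp, at -0.73 ± 0.27 and the cell cycle regulator E2f8 at -1.57 ± 0.60, which was -0.83 without vehicle replicate 3 and 0.30 with the kidney covariate. For both lists 0 members passed when adjusted over the list alone, and DESeq2 called 0. The mean log2 CPM of the ribosomal proteins was 8.03, 8.89 and 9.44 in vehicle replicates 1, 2 and 3. In pegvisomant replicates 1, 2 and 3 it was 8.15, 7.84 and 8.14. For proliferation the means were 5.95, 6.35 and 6.42, and 5.01, 5.92 and 5.96. Vehicle replicate 1 thus lay within the pegvisomant range for both lists. Their members moved together, with estimated correlations of 0.94 and 0.78. Without vehicle replicate 3 the median of the ribosomal proteins was -0.49, and without pegvisomant replicate 1 that of proliferation was -0.32, both past the threshold. Kidney tubule counts were higher in the pegvisomant libraries, as given above, and with the kidney signal as a covariate the medians were 0.17 for ribosomal proteins and -0.14 for proliferation, neither past the threshold.

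Of the other lower lists, oxidative phosphorylation had a median of -0.33 (adjusted p = 1.55e-05; adjusted p = 0.79 with an estimated correlation) with Cox6b1 at -0.58 ± 0.20, and the unfolded protein and integrated stress response -0.53 (adjusted p = 3.87e-04; adjusted p = 0.79 with an estimated correlation) with the chaperone gene Calr at -0.92 ± 0.26 and Asns, which makes asparagine, at -1.73 ± 0.55, and at 0.33 with the kidney covariate. Replication-dependent histones had a median of -0.65 (adjusted p = 0.0073) and neutrophils -1.09 (adjusted p = 0.022), both with adjusted p = 0.79 with an estimated correlation. In the neutrophil list the S100a8 gene was at -2.28 ± 0.85, and at -1.34 without vehicle replicate 3, while Csf3r, the receptor for granulocyte colony-stimulating factor, was at 0.86 ± 0.36, and DESeq2 called 1 member, Clec4e, which was lower. Each of these 4 lists had 0 members past the threshold when adjusted over the list alone. For the unfolded protein response the mean log2 CPM was 6.39 in vehicle replicate 1, within the pegvisomant range of 6.12 to 6.89. For histones it was 2.4 in vehicle replicate 1, below the pegvisomant range of 2.5 to 2.95. With the kidney covariate none of the 4 passed, with medians of -0.15 for oxidative phosphorylation (adjusted p = 0.067), 0.32 for the unfolded protein response (adjusted p = 0.0681), 0.41 for histones (adjusted p = 0.0843) and -0.68 for neutrophils (adjusted p = 0.295). The unfolded protein response did not pass without pegvisomant replicate 3 (-0.39, adjusted p = 0.0909), nor histones without vehicle replicate 3 (-0.27, adjusted p = 0.144) or with the length trend removed (-0.47, adjusted p = 0.0963), and histones were at -1.01 without vehicle replicate 1. Without pegvisomant replicate 3 oxidative phosphorylation was at -0.51, and it was at -0.16 under upper-quartile scaling and -0.15 with library totals alone, past the threshold in each. The neutrophil list did not pass without vehicle replicate 1 (-1.11, adjusted p = 0.101), without pegvisomant replicate 3 (-0.88, adjusted p = 0.193), with the stricter filter (-0.76, adjusted p = 0.521), with quality weights (-0.30, adjusted p = 0.413), with the length trend removed (-1.26, adjusted p = 0.0524) or against vehicle replicate 2 alone (0.22, adjusted p = 0.304).

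The kidney proximal tubule list rose (median 2.12, adjusted p = 4.57e-11), with 32 of 35 members positive, and the list for the loop, distal and collecting tubule rose (median 1.89, adjusted p = 4.57e-11), with all 29 members positive. Both had adjusted p = 0.79 with an estimated correlation. Without vehicle replicate 1 the proximal median was 4.07, over leave-one-out fits it ranged from 1.68 to 4.07. Adjusted over the list alone, 0 proximal and 7 distal members were higher, and DESeq2 called 3 and 6 over all genes, all higher. Slc22a12, the urate transporter of the proximal tubule, was at 11.5 ± 13.3 CPM with vehicle and 74.4 ± 30.7 CPM with pegvisomant, with a log2 fold change of 2.70 over all libraries and 4.28 without vehicle replicate 1, and the water channel gene Aqp3 at 1.28 ± 0.47 and 6.99 ± 3.03 CPM. The skeletal muscle list had a median of 1.36 (adjusted p = 0.0258; adjusted p = 0.79 with an estimated correlation), with Ttn at 2.52 ± 0.96 (1.55 without pegvisomant replicate 2) and Tnnt3 at 2.14 ± 0.71, and did not pass under upper-quartile scaling (1.51, adjusted p = 0.0786), with library totals alone (1.52, adjusted p = 0.0904), the stricter filter (1.31, adjusted p = 0.234), the replicate block (1.45, adjusted p = 0.0598) or the kidney covariate (0.92, adjusted p = 0.595). Nor did it pass without vehicle replicate 3 (1.27, adjusted p = 0.0536), pegvisomant replicate 2 (0.81, adjusted p = 0.312) or pegvisomant replicate 3 (1.42, adjusted p = 0.227), and without vehicle replicate 1 it was at 2.14. Mitochondrially encoded genes had a median of 0.37 (adjusted p = 0.031; adjusted p = 0.79 with an estimated correlation), led by mt-Nd4l at 1.42 ± 0.42, and the median was -0.88 with the kidney signal as a covariate (adjusted p = 0.0292). This list was at 1.03 without vehicle replicate 1, and did not pass without vehicle replicate 2 (0.067, adjusted p = 0.287), vehicle replicate 3 (0.097, adjusted p = 0.112), pegvisomant replicate 1 (0.30, adjusted p = 0.0546) or pegvisomant replicate 3 (0.32, adjusted p = 0.167). Of skeletal muscle and mitochondrially encoded genes 0 members passed when adjusted over the list alone or by DESeq2.

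**Figure D2:**
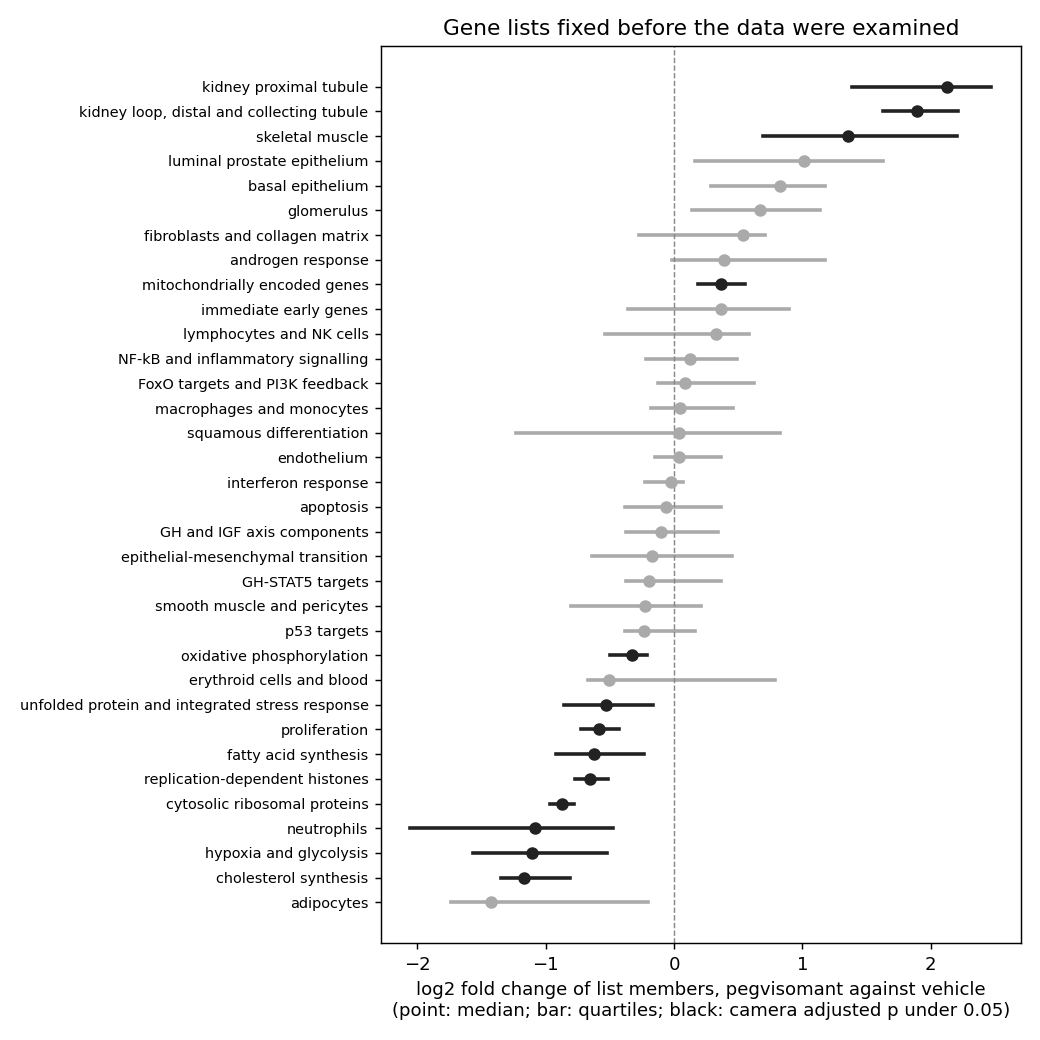
Median log2 fold change (points) and quartiles (bars) of the members of each of the 34 lists, pegvisomant against vehicle; black marks the 13 lists past the camera threshold with the preset correlation. Cholesterol synthesis lay at -1.17 and the kidney proximal tubule at 2.12.

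The lists of the growth hormone axis itself did not pass. The list of growth hormone and STAT5 targets had a median of -0.20 where camera gave the upward direction (adjusted p = 0.615). This median was 0.26 by limma-voom, 0.42 with quality weights, 0.24 with the replicate block, 0.28 with the kidney covariate, 0.54 against vehicle replicate 2 alone and 0.44 without vehicle replicate 1, and the list passed in none of these. The list of growth hormone and insulin-like growth factor components had a median of -0.11 (adjusted p = 0.796), which was 0.06 under upper-quartile scaling, 0.08 with library totals alone, 0.10 by limma-voom, 0.22 with quality weights, 0.05 with the replicate block, 0.34 against vehicle replicate 2 alone and 0.33 without vehicle replicate 1. Ghr, the receptor that pegvisomant blocks, was at 202 ± 102 CPM with vehicle and 159 ± 27.5 CPM with pegvisomant (log2 fold change -0.35 ± 0.38, adjusted p = 0.599). The feedback inhibitor Socs2 was at 20.4 ± 3.41 and 18.6 ± 7.63 CPM, and Cish, another STAT5-induced inhibitor, at 3.29 ± 1.55 and 6.46 ± 1.23 CPM (adjusted p = 0.31). Igf1 was at 240 CPM in vehicle replicate 1, where the hepatocyte list took 4.48% of counts. It was at 20.6 and 8.87 CPM in vehicle replicates 2 and 3, against 39.7, 107 and 67.4 CPM with pegvisomant. Its log2 fold change was -0.33 ± 1.15 over all libraries and 2.26 ± 0.54 without vehicle replicate 1 (adjusted p = 0.0488). In the latter fit kidney tubule genes took 0.0917 and 0.0634% of counts with vehicle and between 0.745 and 1.43% with pegvisomant. Fold changes were 0.64 ± 0.32 for Igf1r, 0.29 ± 0.29 for Stat5a, 0.22 ± 0.23 for Stat5b, 0.27 ± 0.20 for the kinase gene Jak2, and 0.05 ± 0.30 for Pten, whose counts per gene cannot show a deletion of part of the gene. With 1 library left out these ranged from 0.34 to 0.90, from 0.12 to 0.38, from 0.12 to 0.40, from 0.098 to 0.353 and from -0.22 to 0.32, and with the kidney covariate Stat5a was at -0.005, Stat5b at -0.25 and Pten at -0.52. The proliferation marker Mki67 was at -0.08 ± 0.36, and at 0.07 and 0.09 under upper-quartile scaling and with library totals alone, where Socs2 was at 0.03 and 0.02. When adjusted over the list alone, 1 of 32 components passed. That gene was Igfbp3 (chromosome 11, 7206086 to 7213923 on GRCm38, ENSMUSG00000020427), with a log2 fold change of -1.60 ± 0.23. Stc1, an inhibitor of the protease that frees insulin-like growth factors, was at -1.84 ± 0.41. DESeq2 called it over all genes (adjusted p = 0.0194), and edgeR did so without vehicle replicate 1 (adjusted p = 0.0212). The STAT5 target Ccnd1, cyclin D1, was at -1.62 ± 0.65, with vehicle libraries between 187.9 and 1344 CPM. Ccnd1 was at -0.81 without vehicle replicate 3, at -2.09 without vehicle replicate 1 (adjusted p = 0.0306) and at 0.81 with the kidney covariate.

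The 5 genes per direction with the smallest unadjusted p, leaving out predicted, clone and pseudogene symbols, are given as values, since edgeR called none over all 6 libraries (adjusted p = 0.302 for each). DESeq2, run on the same 6 libraries and so no independent test, called all 10, with adjusted p between 4.41e-12 (Hao1) and 0.0386 (Aff1). Over 3 simulations together its calls included 224 of 54444 unchanged genes, as given above. How these divide by adjusted p was not examined. On the lower side, besides Igfbp3, Hao1 (ENSMUSG00000027261, chromosome 2, 134497361 to 134554368), a peroxisomal glycolate oxidase, was at 30.8 ± 15.6 CPM with vehicle and 1.00 ± 0.58 CPM with pegvisomant. Gpt2 (ENSMUSG00000031700, chromosome 8, 85492576 to 85527560), the mitochondrial alanine aminotransferase, was at 96.7 ± 10.7 and 41.0 ± 3.31 CPM. Nrn1, a neurite growth factor, had a log2 fold change of -3.27 ± 0.46 and Mctp2 of -2.67 ± 0.40. On the higher side, Tmem252 (ENSMUSG00000048572, chromosome 19, 24674008 to 24682233) was at 11.7 ± 1.76 and 42.7 ± 13.96 CPM. Aff1, a transcription elongation factor, was at 87.4 ± 14.9 and 175 ± 17.5 CPM. Trabd2b was at 1.62 ± 0.29, Cmya5 at 2.07 ± 0.40 and Snhg11 at 4.29 ± 0.83.

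**Figure D3:**
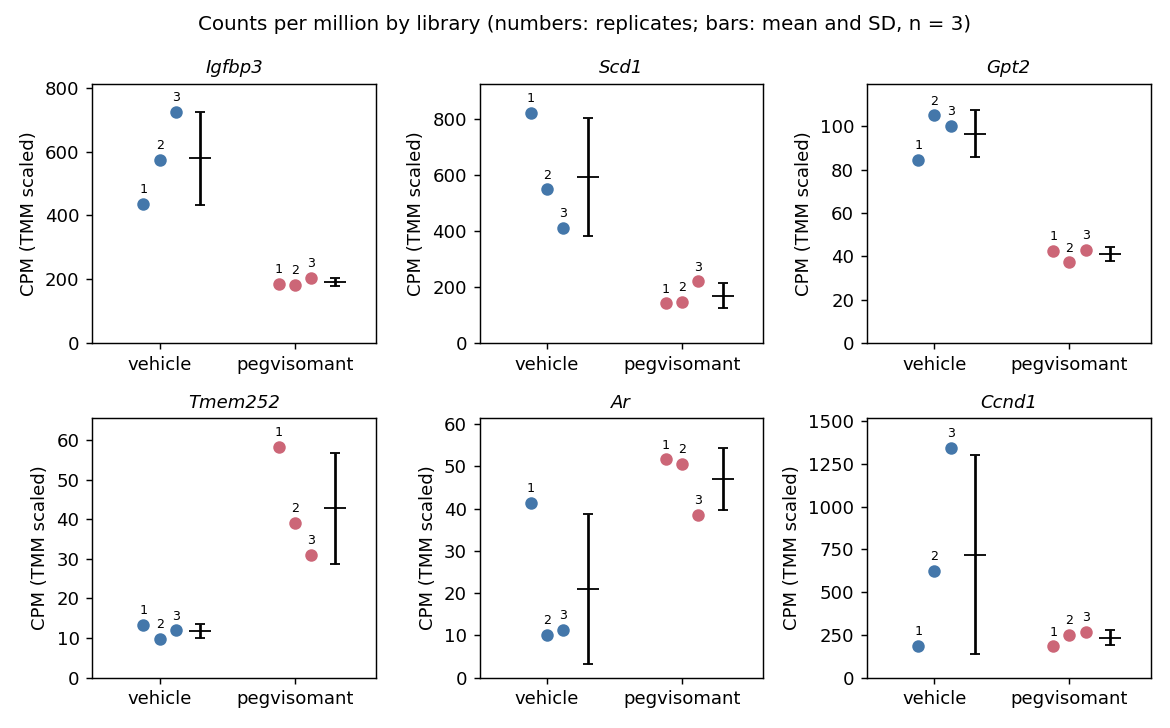
TMM-scaled CPM of 6 genes in each library (numbered points) with the mean and SD of each group (n = 3). Igfbp3 was between 183 and 204.2 CPM in the pegvisomant libraries and between 435 and 726 CPM in the vehicle libraries, and for Ar vehicle replicate 1 lay apart from the other vehicle libraries.

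Without vehicle replicate 1 edgeR compared 2 vehicle with 3 pegvisomant libraries over 19172 genes. Of the 1956 genes called, 1915 were also tested over all 6 libraries and 1752 of these had the same sign there. The calls shared 167 genes with the 290 of DESeq2 and 1574 with the 3018 of limma-voom with quality weights. They included 43 genes of the kidney tubule lists and 18 of the hepatocyte list, and the library left out was the vehicle library with the most kidney tubule counts. In the libraries kept, the hepatocyte list was higher with pegvisomant. It took 0.00489 and 0.00367% of vehicle replicates 2 and 3 and between 0.0219 and 0.0496% of the pegvisomant libraries. The 10 genes given above by unadjusted p under that symbol rule, Igfbp3 included, all passed in this fit with the same sign. They were chosen from the same libraries, of which this fit keeps 5, so that this is no independent test. Igfbp3 fell by 1.78 ± 0.19 (adjusted p = 0.0186) and Gpt2 by 1.34 ± 0.16 (adjusted p = 0.0208), on the log2 scale. Of the cytosolic ribosomal proteins 37 of 44 fell and none rose, of the unfolded protein and integrated stress response 11 of 36 fell, and of hypoxia and glycolysis 9 of 33 fell, among them Slc16a3 (-2.63 ± 0.35) and Pkm (-1.85 ± 0.36). The androgen receptor gene Ar (ENSMUSG00000046532, chromosome X, 98148769 to 98323215) rose by 2.12 ± 0.23 (adjusted p = 0.0186), against 1.17 ± 0.57 over all libraries (adjusted p = 0.326), with 41.4 CPM in vehicle replicate 1 and 10.2 and 11.3 CPM in the others, where kidney tubule genes took 0.654, 0.0917 and 0.0634% of counts. With the kidney covariate over all 6 libraries, a fit that rests largely on vehicle replicate 1, Ar was at -0.091. Of the androgen response list 7 of 24 rose and 2 fell (camera adjusted p = 0.0106, against 0.117 over all libraries), and of luminal prostate epithelium 2 of 21 rose (median 2.00, camera adjusted p = 0.039, against 0.118). Over all 19172 genes of this fit 1103 rose and 853 fell. The difference in kidney tubule counts applies to this fit as a whole, and its part in these 2 lists was not tested. With an estimated correlation, tried in this fit after the data were seen, 0 lists passed, and both had adjusted p = 0.698. Leaving out any other library gave 0 genes by edgeR.

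The other lists did not pass by camera over all 6 libraries. Their medians were 1.01 for luminal prostate epithelium (adjusted p = 0.118), 0.82 for basal epithelium (adjusted p = 0.117), 0.54 for fibroblasts and collagen matrix (adjusted p = 0.117), 0.39 for androgen response and 0.67 for the glomerulus (adjusted p = 0.174). The medians were -0.06 for apoptosis, -0.23 for p53 targets, 0.08 for FoxO targets and PI3K feedback, 0.04 for squamous differentiation and -0.17 for epithelial-mesenchymal transition. Interferon response (-0.02), inflammatory signalling through NF-kB (0.12) and immediate early genes (0.36) did not pass either. Among cell type lists the medians were -0.22 for smooth muscle and pericytes, 0.04 for endothelium, 0.05 for macrophages and monocytes, 0.32 for lymphocytes and NK cells, -1.43 for adipocytes and -0.51 for erythroid cells and blood. The adjusted p of these 14 lists without a printed value lay between 0.469 and 0.845. For erythroid cells the median was negative while the mean and the test direction were upward, and for squamous differentiation, endothelium, macrophages and lymphocytes the mean was negative while the median and the test direction were upward. Medians in this paragraph depended on vehicle replicate 1. Without it they were, among others, 1.19 for fibroblasts and collagen matrix, 1.37 for the glomerulus and 1.1 for androgen response. Endothelium was then at 0.59, adipocytes at -0.88, and smooth muscle and pericytes at 0.55.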

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

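Of the alternatives in this part, the robust prior, the removal of the length trend, vehicle replicate 2 alone and an estimated correlation without vehicle replicate 1 were chosen after the results were seen. The count of 0 genes was kept under other scalings and filters, limma-voom, effective length offsets, the robust prior, the length trend, vehicle replicate 2 alone and without any library but vehicle replicate 1. DESeq2 gave 290 genes, limma-voom with quality weights 3018, the kidney covariate 367, and leaving out 1 library between 0 and 1956, the latter without vehicle replicate 1. Of the 367, 360 had their highest CPM in vehicle replicate 1 and 25 were the whole hepatocyte list. At an unadjusted p under 0.05 the 3010 genes became 7779 with quality weights, 1516 with the kidney covariate, 1223 against 1.5-fold, and between 1032 and 7352 with a library left out. The 13 lists became 8 with the kidney covariate, and between 9 and 14 with a library left out. They became 0 with an estimated correlation, over all libraries or without vehicle replicate 1, and 0 by fry. Of the 13, only hypoxia and glycolysis, cholesterol synthesis, fatty acid synthesis and, in the opposite direction, mitochondrially encoded genes passed with the covariate. The rest of the 8 were lists outside the 13. The covariate is made from the tubule lists and so removes them by construction. The mean log2 CPM of the proximal tubule list was 6.32, 3.04 and 2.7 in vehicle replicates 1, 2 and 3. With pegvisomant it was between 6.32 and 7.35. Only vehicle replicate 1 thus had a tubule level like that of the pegvisomant libraries. The fit with the covariate rests largely on that library, which also held the liver transcripts. Replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.112, -0.009 and 0.058). The replicate block gave 0 genes, 3209 at the unadjusted threshold and 13 lists. Over 329 list values in these settings 252 kept the direction of the list test and side of the threshold, 65 lost the threshold and 12 changed that direction. A median could change sign without a change of that direction. For GH-STAT5 targets it went from -0.196 to 0.261 by limma-voom and counts as kept. Over 1727 values of named genes 1580 were the same, 109 passed where they had not and 38 changed sign. The cause of the changes was not tested. Depth limits genes near the floor most in pegvisomant replicate 2, with 13516141 counts.

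With the kidney covariate, list medians were 0.32 for the unfolded protein response, 0.27 for the proximal tubule, 0.17 for ribosomal proteins, -0.88 for mitochondrially encoded genes, 0.41 for histones and 0.28 for GH-STAT5 targets, and gene values were Socs2 0.16, Stat5a -0.005, Stat5b -0.25, Pten -0.52, Ar -0.091, Ccnd1 0.81, E2f8 0.30, Pdia6 0.022, Asns 0.33, Hist1h4d 0.15, Hist1h3d 0.20 and Hist1h4a 0.58. Limma-voom gave Igf1 1.03 and Mup3 0.83. With quality weights the growth hormone axis list was at 0.22, Ghr 0.18, Igf1 1.81, Mki67 0.038, Mup3 4.25 and Prlr 0.56. With the replicate block Igf1 was at 1.28 and Mup3 at 3.25. Upper-quartile scaling gave Socs2 0.03 and Mki67 0.073, and library totals alone Socs2 0.021 and Mki67 0.092. The stricter filter put the axis list at -0.011 with an upward test direction, and removal of the length trend put Pten at -0.19. Against vehicle replicate 2 alone the axis list was at 0.34, Ghr 0.43, Igf1 1.76, Pten -0.025, Mup3 5.86 and Prlr 1.53. With a library left out, GH-STAT5 targets ranged from -0.091 to 0.442, the axis list from -0.18 to 0.33, Ghr from -0.64 to 0.11, Igf1 from -0.88 to 2.26, Socs2 from -0.518 to 0.064, Pten from -0.22 to 0.32, Mki67 from -0.31 to 0.18 and Mup3 from -6.85 to 4.82. Mup3, also a member of the hepatocyte list, was at 973 CPM in vehicle replicate 1 and at most 10.2 CPM in any other library.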

Other observations

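Tests of kidney tissue, of variable dissection and of class II cells were chosen only after the results were seen, as was the use of vehicle replicate 2 alone and the removal of a length trend. Further immune and signalling genes were among those whose groups did not overlap, though edgeR called none of those named here over all 6 libraries. DESeq2 called Arg1 (adjusted p = 6.68e-05), Ptges (adjusted p = 0.0382), Arc (adjusted p = 0.0279) and Pdk4 (adjusted p = 0.0398). Over 3 simulations together DESeq2 called 224 of 54444 unchanged genes (0.411%) where edgeR called 8, so these DESeq2 calls are weak evidence on their own. How such false calls divide by adjusted p was not examined. Arg1, an arginase of hepatocytes and of alternatively activated macrophages, was at 161, 5.64 and 31.6 CPM in vehicle replicates 1, 2 and 3, where the hepatocyte list took 4.48% of replicate 1, and at 1.85 ± 0.68 CPM (SD, n = 3) with pegvisomant. Its log2 fold change by edgeR was -5.15 ± 1.24 over all libraries and -3.33 ± 0.72 without vehicle replicate 1 (adjusted p = 0.0425). Ptges, a prostaglandin E synthase, was at 39.6, 79.4 and 274 CPM in vehicle replicates 1, 2 and 3 and at 23.9 ± 7.39 CPM with pegvisomant. The immediate early gene Arc was at 2.33 ± 0.73 and 15.2 ± 10.9 CPM, and Pdk4, a FoxO target, at 3.25 ± 1.32 and 13.1 ± 7.92 CPM.

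Kidney tubule lists were higher in the pegvisomant libraries. Host kidney tissue carried over with the graft is a candidate explanation that stays open, since the 95.3% of tested members of both lists with a positive fold change restates the pattern, and the glomerulus list, outside of it, did not pass (median 0.67, adjusted p = 0.174). Whether dissection varied from graft to graft regardless of treatment cannot be told apart from a difference between the groups, because the exact permutation p of the list mean was 0.1, the smallest that 10 splits allow (difference 2.379, highest other split 2.254). An effect of the treatment itself on these lists also stays open, untested.

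The lists for hypoxia and glycolysis, cholesterol synthesis, ribosomal proteins and proliferation were lower with pegvisomant, with a mean of their 4 medians of -0.933. The tables argue against a length trend as the whole cause, since the mean was -0.914 once the trend was removed and all 4 lists still passed. Liver and adrenal transcripts stay open, since vehicle replicate 2 alone is a single library, assumed to vary like the others, and excludes nothing: against it the mean was -0.733 with all 4 lists past the threshold and cholesterol synthesis at -0.504 instead of -1.17, while the mean was -1.08 without vehicle replicate 1 and -0.629 without vehicle replicate 3. Dilution of graft RNA by kidney tissue cannot be told apart from the treatment, because the mean was -0.324 with the kidney signal as a covariate, 2 of the 4 lists passed, and that signal moves with the groups. The fit with the covariate also rests largely on vehicle replicate 1. An effect of the treatment itself stays open and was not tested.

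The transcript of the class II gene H2-Ea (annotated as H2-Ea-ps, a polymorphic pseudogene on chromosome 17, 34341959 to 34344645), singled out after its values were seen, had 0, 8 and 8 counts in vehicle replicates 1, 2 and 3 and 1042, 463 and 705 with pegvisomant (edgeR adjusted p = 0.302 over all libraries and 0.0143 without vehicle replicate 1; DESeq2 adjusted p = 2.87e-24). Fewer class II cells with vehicle would lower H2-Eb1 alike, but H2-Ea per 1000 H2-Eb1 counts was 5.28 with vehicle and 316 with pegvisomant, a ratio of 59.9. Some mouse haplotypes express no H2-Ea, so a difference in the genotype of hosts or cells between the groups may account for it. That cannot be told apart from chance on the count of genes on in 1 group and off in the other, which was 3 (Grip2, Gm26675 and Gm49388) for the real split and at most 2 for any other. The labels give the same host strain for both groups.

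Whether chance can be excluded could not be settled by regrouping, since the 6 libraries make 10 splits. The real split gave 0 genes, as did all 10, with a highest other of 0. At the unadjusted threshold it gave 3010 genes and the highest other split 3410, so that 2 of 10 were as large. That other split exchanged vehicle replicate 1 and pegvisomant replicate 3. The 4 splits with vehicle replicates 2 and 3 on one side gave between 1346 and 3410 genes, and the 6 that parted them between 160 and 442. For lists the real split gave 13 and the other splits between 9 and 16, with 5 of 10 as large. The number of lists past the preset-correlation threshold thus did not set the real split apart.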
